A study of Mus musculus with 24 samples.

How the data were processed

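The series measured RNA in mouse naive CD4 T cells, sorted from spleen and lymph nodes by surface markers that included CD4+, CD44lo and CD25-, with Affymetrix HT MG-430 PM arrays. Cells came from wild-type mice, whose label also gives the strain C57BL/6, and from CD4(cre)Raptor(fl/fl) mice, called Raptor-deficient here. Raptor is the defining subunit of the kinase complex mTORC1, and the Cre recombinase under the Cd4 promoter removes the floxed exon in T cells. RNA was taken without stimulation, or after 8 h or 24 h on plates coated with antibodies to CD3 and CD28. Each of the 6 groups held 4 samples, 24 in all. From each sample 20 ng of RNA were amplified and biotin-labelled with NuGEN kits. Nothing in the labels says that the replicates came from separate animals, so the p-values measure the spread between these samples, part of which may be technical. The gene Slc15a2 was low in wild-type replicates 1 and 3 and high in 2 and 4, unstimulated, at 8 h and at 24 h. That gene, chosen after its values were seen, argues against all wild-type replicates being repeats of 1 source.

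The value table deposited by the authors holds log2 intensities, per the labels made with RMA and Partek 6.5. Values ran from 1.64 to 13.8, the array medians lay between 5.15 and 5.29, and the sorted values of any 2 arrays differed by at most 0.248. The table had 45141 probe sets, of which 28898 named 1 gene symbol, 551 named several, and 15692 were not listed in the gene table. All 104 control probe sets were among the unlisted. The Entrez numbers of 28689 probe sets were found in the RefSeq gene table of assembly GRCm38.p6, which served for gene names and for which genes neighbour each other. For each gene the probe set with the highest mean over all 24 samples was used, which left 17097 genes, 7180 of them with over 1 probe set. No level filter was applied, and the number of arrays limits the precision.

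Genes were tested with limma 3.58.1 in R 4.3.3. One linear model with 6 group means was fitted to all 24 samples, with 18 residual degrees of freedom, followed by empirical Bayes moderation with neither an intensity trend nor a robust prior. Benjamini-Hochberg adjustment was done within each of 11 comparisons. A gene was called at an adjusted p under 0.05, and the number of called genes with a fold of at least 2 is given beside that count. The tests are two-sided. The comparisons were Raptor-deficient against wild type at each time, each time against unstimulated cells within each genotype, 24 h against 8 h in wild type, and 3 differences between genotypes in a response. The share of the wild-type response seen in Raptor-deficient cells is a slope through the origin across genes, with its SD over the 4 stimulated Raptor-deficient samples. Genes are not independent replicates, so no p is given for it.

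Before the data were examined, 21 pathway lists and 9 lists of other cell types were written from general knowledge, together with the tests and alternatives. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a kind within a comparison. Camera with a correlation estimated for each list was the alternative. For most lists, counts of members adjusted over the list alone stand beside those over all genes. Named genes are the 10 largest rises and the 10 largest falls among called genes whose higher group mean was at or above the median of all values, 5.51. For comparisons of 2 groups, all 4 samples of one group also had to lie above all 4 of the other. A group mean under that median lies near background, where folds are those of the measured intensities only, as for Fasl, Ccr8, Asns, Scd1 and Pax5. Gene models without a proper symbol were passed over. Further named genes are up to 4 called members with the smallest p of each pathway list, and a fixed set of genes that included Rptor, Mtor, Rictor, Myc, Hif1a, Irf4, Il2, Il2ra, Cd69, Il4ra, Gata3, Tbx21, Srebf2, Hk2, Slc2a1 and Klf2. Srebf1, Il7r and Ccr7 of that set were not analysed here, and 1 further gene of it is not reported here. Members of the cell type lists, the liver genes, and the genes named as exceptions in the text were chosen after their values were seen.

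The pipeline was tested on simulated data with the same design, in which 200 of 17097 genes were changed at 24 h. It recovered 82.1% of 67 genes changed 1.5-fold, 98.5% of 67 changed 2-fold and 100% of 66 changed 4-fold, with 8 false calls and 0 calls in an unchanged comparison. A raised list was called, and of the 21 simulated lists 0 unchanged ones were. A slope of 0.7 was recovered as 0.699. The noise was independent between genes and equal in all groups, so correlation within lists and a group with a larger spread were not tried. The genes of the slope all changed by 2 on the log2 scale in wild type, so a bias from choosing them could not show.

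Alternatives were the mean of all probe sets of a gene, a filter that kept genes at or above the median of all values in at least 4 samples, cyclic loess between arrays, centring of each array on genes between the 40 and 60 percentiles of variance, array weights, an intensity trend with a robust prior, fits to the compared groups alone, the replicate number as a block, and each sample left out in turn. For the slopes, no fold minimum and genes chosen in part of the wild-type samples were also tried.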

Results

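The data were 24 arrays, 4 in each of 6 groups of sorted naive CD4 T cells, wild type or Raptor-deficient, unstimulated or stimulated through CD3 and CD28 for 8 h or 24 h. Principal component 1 held 59.8% of the variance and separated unstimulated from stimulated cells, and component 2 held 16.8%. On component 1 the wild-type samples lay at 48.0 to 53.6 at 24 h and the Raptor-deficient ones at 24.5 to 33.5. Replicates correlated with a Pearson r across genes of at least 0.978. Unstimulated Raptor-deficient replicate 1 stood apart, with 377 genes at least 2-fold away from the mean of the other 3 replicates, 342 of them higher. Its residual SD was 0.280. Replicates 2 and 3 of that group followed with 0.222 and 0.206 and with 87 and 54 such genes, and the other 21 arrays lay between 0.119 and 0.172.

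**Figure D1:**
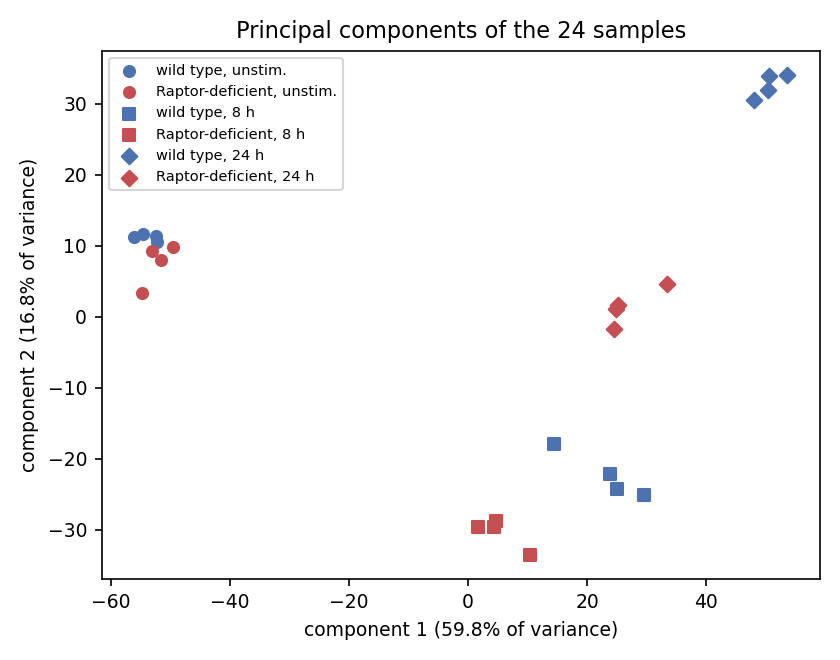
Each point is 1 of the 24 samples, placed by its scores on principal components 1 and 2, whose shares of variance are 59.8% and 16.8%. Colour gives the genotype and shape the time; at 24 h the genotypes separate on both components.

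Rptor, the gene that the Cre recombinase targets, was measured by 2 probe sets in every sample. The brighter one averaged 7.28 ± 0.20 (SD, n = 4) in unstimulated wild-type and 6.66 ± 0.60 in unstimulated Raptor-deficient cells, a difference that did not pass the test (adjusted p = 0.075). Unstimulated Raptor-deficient replicate 2, at 7.37, lay within the wild-type range. With 8 h of stimulation it was 2.02-fold lower (7.51 ± 0.04 against 6.49 ± 0.22, adjusted p = 0.000292) and at 24 h 1.56-fold lower (adjusted p = 0.0109, or 0.0675 without replicate 1 of both 24 h groups, which was tried after seeing the data). The other probe set differed by -0.58, -0.66 and -0.60 on the log2 scale at the 3 times, with adjusted p = 0.000762, 2.45e-05 and 2.83e-05 over all probe sets. The files do not place the probes against the deleted exon, so these values say little about how complete the deletion was. Mtor, the kinase of the complex, was not called at any time, with adjusted p = 0.603, 0.989 and 0.506.

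In wild-type cells, stimulation for 8 h raised early activation genes strongly. The cytokine gene Il2 rose from 4.43 ± 0.35 to 11.56 ± 0.29 (SD, n = 4 each, 140-fold), Il2ra, a chain of its receptor, rose 76.1-fold and the transcription factor gene Irf4 51.8-fold. Unstimulated Il2 and Il2ra (3.97) lay under the median of all values, near background, so their folds are only those of the measured intensities. Of the 39 measured T cell activation genes, 34 rose and 0 fell (35 and 0 adjusted over the list alone), among them Nr4a1 (by 4.81 on the log2 scale), Myc (by 4.25) and Cd69 (13.9-fold). Ribosome biogenesis genes rose in 37 of 38 cases, with Nhp2 up 10.1-fold, and sterol synthesis and uptake genes in 17 of 19, with 1 lower and Sqle up 12.7-fold, also from a level near background (3.95). Oxidative phosphorylation had 47 of 54 genes up and 1 down. In the one-carbon, serine and nucleotide synthesis list 22 of 23 rose and 0 fell. Naive and quiescence genes moved the other way, with 18 of 24 down and 2 up, among them Txnip (4.07-fold lower), and S1pr1, a receptor for leaving lymph nodes, was 5.97-fold lower. The counts of these last 5 lists were the same adjusted over the list alone. With the preset correlation these 6 lists had adjusted p values of 7.6e-09 or less, and with an estimated correlation of 0.043 or less. Tricarboxylic acid cycle genes, 11 of 18 up and 3 down (11 and 4 adjusted over the list alone), passed at 0.011 but had adjusted p = 0.30 with an estimated correlation, and lost the call with cyclic loess (0.0892) and with the dim filter (0.0911). Of 3455 called genes with over 1 probe set, 115 had called probe sets of opposite direction, among them the list members Atp5c1, Higd1a, Ndufb8, Ogdh, Rora and Cd160. In all, 6784 genes were called, 3229 higher and 3555 lower, 1830 of them with a fold of at least 2.

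By 24 h in wild-type cells, cell cycle genes had risen as well. Mki67, a marker of dividing cells, went from 5.54 ± 0.19 to 10.98 ± 0.03 (SD, n = 4 each, 43.5-fold), and Aurkb, a mitotic kinase gene, rose 15.7-fold from 4.23, a level near background. G2 and M phase genes rose in 32 of 34 cases and fell in 2, and G1 and S phase genes rose in 37 of 39 and fell in 2 (adjusted p = 1.4e-19 and 9.9e-23, the same counts adjusted over the list alone). Glycolysis had 15 of 17 genes up and 1 down (the same adjusted over the list alone), with the glucose transporter gene Slc2a1 up 4.47-fold. Tbx21, which encodes the Th1 factor T-bet, went from 3.17, near background, to 7.96, while Gata3, which encodes a Th2 factor, differed by -0.05 on the log2 scale (adjusted p = 0.825). Klf2, a quiescence factor gene, fell 8.32-fold. Of the regulatory T cell markers 7 of 8 rose (adjusted p = 0.00046, the same count adjusted over the list alone), a list that shares Il2ra and Ctla4 with the activation genes. Of 8496 called genes, 4348 were higher and 4148 lower, 2797 with a fold of at least 2. Of 4122 called genes with over 1 probe set, 360 had called probe sets of opposite direction, 18 of them members of the lists, such as Ccnd3, Orc1, Idh2, Pdhb and Uqcrq. Between 8 h and 24 h, 4845 genes were called, 2967 higher and 1878 lower. Replicate 1 of both 24 h groups carried liver transcripts, with albumin (Alb) at 9.02 in wild-type and 9.11 in Raptor-deficient cells against 6.22 to 6.42 in the other 24 h samples.

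Unstimulated Raptor-deficient cells, compared with wild type to see what the loss of Raptor does before any stimulus, differed in the activation marker Cd69 among others. Cd69, an early activation marker, averaged 7.85 ± 0.27 against 6.63 ± 0.26 (SD, n = 4 each, 2.32-fold higher, adjusted p = 6.19e-07). Fosl2, an AP-1 subunit gene, was 2.85-fold higher (adjusted p = 2.79e-09), Rragd, a GTPase gene of the amino acid signal to mTORC1, 2.57-fold and the transcription factor gene Myb 2.56-fold. The genes lowered the most included Klrd1, a lectin receptor gene of the NK cell list (3.14-fold), Map3k5, a stress kinase gene (3.03-fold), Atxn1 (2.52-fold) and Dnajc15 (2.51-fold). Among the T cell activation genes 4 of 39 were higher and 2 lower (14 and 4 adjusted over the list alone; 1 lower without wild-type unstimulated replicates 1, 2 or 3 or Raptor-deficient unstimulated replicates 1 or 2), with Egr1 up 1.78-fold and Ctla4 down 1.83-fold. That list passed camera at an adjusted p of 9.7e-06, with adjusted p = 0.069 with an estimated correlation. Lysosome and autophagy genes, 3 of 31 higher and 0 lower (5 and 0 adjusted over the list alone), passed at 0.00043, again with adjusted p = 0.069 with an estimated correlation. Of these genes, Tpp1 and Lamp2 lost their calls with only the unstimulated samples in the fit. Lamp2 was also not called without wild-type unstimulated replicates 1 or 3 or Raptor-deficient unstimulated replicates 2, 3 or 4. Tpp1 was also not called without replicate 2 of either unstimulated group, or with the mean of all its probe sets. Cytosolic ribosomal proteins passed at 0.0087 with 0 of 32 members called and a median of 0.05, but had adjusted p = 0.84 with an estimated correlation, 0.153 with cyclic loess, 0.0563 with array weights, 0.0681 without wild-type unstimulated replicate 4 and 0.278 without Raptor-deficient unstimulated replicate 1.

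Markers of other cells also moved in the unstimulated comparison. The B cell list was higher by a median of 0.25 with 0 of 14 members called (adjusted p = 0.0030, adjusted p = 0.25 with an estimated correlation), and had an adjusted p of 0.0982 without Raptor-deficient unstimulated replicate 1, 0.110 without that library and wild-type 8 h replicate 1, 0.108 with the dim filter and 0.170 with array weights. Of the alpha beta CD4 T cell markers 3 of 11 were lower and 0 higher (5 and 0 adjusted over the list alone), with Cd6 1.62-fold lower (list adjusted p = 0.012, adjusted p = 0.16 with an estimated correlation, 0.0667 without Raptor-deficient unstimulated replicate 3, 0.243 without replicates 2 and 3 of that group, 0.0617 with the dim filter and 0.0503 with array weights). Without Raptor-deficient unstimulated replicate 3 the median of that list turned from -0.0386 to 0.0044, and 1 member was called without wild-type unstimulated replicates 2, 3 or 4 or Raptor-deficient unstimulated replicate 1. No other pathway or cell type list was called at this time. In the glycolysis, mitochondrial translation, interferon, PI3K, Akt and mTOR component and NK cell lists the median, the mean and the test differed in sign. In all, 332 genes were called, 120 higher and 212 lower, 20 with a fold of at least 2 (6 higher and 14 lower). The last count was 35 (20 and 15) without Raptor-deficient unstimulated replicate 3 and 63 (51 and 12) without replicates 2 and 3 of that group. The count was 52 when only the unstimulated samples entered the fit, 179 with array weights, 196, 207 and 216 without wild-type unstimulated replicates 3, 1 and 2, and 718 without Raptor-deficient unstimulated replicate 3. It was also 718, with 396 higher and 322 lower, without replicates 2 and 3 of that group, which was tried after seeing the data. Centring of the arrays gave 156 higher and 170 lower.

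Slc15a2, a peptide transporter gene, had the largest rise in unstimulated cells, 3.83 on the log2 scale (adjusted p = 0.0489), but its wild-type samples fell into separate levels. Wild-type replicates 1 and 3 lay at 3.22 and 3.41 and replicates 2 and 4 at 8.404 and 8.521, and the Raptor-deficient samples lay between 8.92 and 10.56. The same wild-type replicates were low at 8 h (3.44 and 3.46) and at 24 h (3.68 and 3.61). Its call was lost, with adjusted p between 0.0511 and 0.198, when 1 sample was left out among wild-type unstimulated replicates 1 and 3, Raptor-deficient unstimulated replicates 1, 2 and 4, the 4 Raptor-deficient 8 h samples or any of the 24 h samples. It was also lost with array weights (0.178), with an intensity trend and robust prior (0.115), with only the unstimulated samples in the fit (0.268) and with the mean of all its probe sets, where the rise was 1.23 on the log2 scale (0.0799).

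At 8 h, genes of sterol synthesis were the group that differed most between genotypes. Cyp51, a sterol demethylase gene, reached 9.61 ± 0.05 in wild-type and 7.69 ± 0.24 in Raptor-deficient cells (SD, n = 4 each, 3.79-fold lower, adjusted p = 1.01e-11). Of the 19 measured genes of sterol synthesis and uptake, 18 were lower and 0 higher (19 and 0 adjusted over the list alone), with a median of -1.21, among them Dhcr7 (2.46-fold), Sc5d (2.77-fold) and Stard4 (2.16-fold). Srebf2, which encodes a regulator of these genes, was 1.45-fold lower (adjusted p = 0.00107). Fatty acid synthesis had 6 of 13 genes lower and 0 higher (6 and 0 adjusted over the list alone), with Acsl3 at 2.05-fold and Fasn at 1.75-fold.

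Genes of energy metabolism and of growth were lower at 8 h as well. Oxidative phosphorylation had 46 of 54 genes lower and 0 higher (49 and 0 adjusted over the list alone), with a median of -0.48 and Cyc1 1.51-fold lower. In glycolysis 9 of 17 genes were lower and 1 higher (the same adjusted over the list alone; 0 higher without replicate 3 of either 8 h group), with Ldha 1.67-fold and Pgk1 1.69-fold lower. The tricarboxylic acid cycle list had 10 of 18 lower, mitochondrial translation 21 of 30, ribosome biogenesis 20 of 38 and one-carbon, serine and nucleotide synthesis 14 of 23, each with 0 higher (11, 25, 29 and 15 lower and 0 higher adjusted over the list alone). The unfolded protein response list had 13 of 22 lower and 1 higher (16 and 1 adjusted over the list alone), with Sdf2l1, a chaperone cofactor gene, 2.43-fold lower. All these lists passed camera with adjusted p of 0.00022 or less, and with an estimated correlation they passed too, the largest being the tricarboxylic acid cycle at 0.032. Amino acid response genes, 9 of 31 lower and 2 higher (12 and 2 adjusted over the list alone; 1 higher without wild-type 8 h replicates 2, 3 or 4 or Raptor-deficient 8 h replicates 2 or 4), and G1 and S phase genes, 9 of 39 lower and 3 higher (13 and 3), passed at 0.028 and 0.0012, but each had adjusted p = 0.16 with an estimated correlation. The first lost its call with cyclic loess (0.140), without wild-type 8 h replicate 3 (0.0578) and without Raptor-deficient 8 h replicates 1 (0.0588) and 4 (0.105), and the second with the dim filter (0.0689). G1 and S phase had 3 genes lower without wild-type 8 h replicate 2 and 5 without Raptor-deficient 8 h replicate 4. Cytosolic ribosomal proteins, 5 of 32 higher and 1 lower (6 and 1 adjusted over the list alone), passed at 0.0020 with a median of 0.12, with adjusted p = 0.23 with an estimated correlation, and with 3 higher without wild-type 8 h replicates 2, 3 or 4 or Raptor-deficient 8 h replicates 1, 2 or 4.

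Activation genes differed in both directions at 8 h. Of 39, 12 were higher and 8 lower (13 and 11 adjusted over the list alone), and the list was not called (adjusted p = 0.29). Hif1a, which encodes the oxygen-sensing factor, was 2.04-fold lower (10.11 ± 0.12 against 9.09 ± 0.10, SD, n = 4 each) and Il2 1.78-fold lower, while the chemokine gene Xcl1 was 3.29-fold higher. Myc and Irf4 were not called, with log2 differences of 0.14 and -0.24 (adjusted p = 0.431 and 0.462). The largest fall was that of Fasl, the death ligand gene (6.45-fold). Rgs1 was 3.56-fold and the thrombin receptor gene F2r 3.49-fold lower, and Ccr8, a chemokine receptor gene, was 5.09-fold higher. Naive and quiescence genes were higher in 10 of 24 cases and lower in 2 (14 and 4 adjusted over the list alone), with Satb1 2.14-fold and Klf6 1.76-fold higher; the list passed at 0.00016, with adjusted p = 0.19 with an estimated correlation, and with 6 higher without wild-type 8 h replicate 3. The G2 and M phase, helper lineage, hypoxia, lysosome, interferon, p53 and PI3K, Akt and mTOR component lists were not called. In the G2 and M phase and lysosome lists the median, the mean and the test differed in sign.

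Other cells' markers at 8 h moved beside these groups. Myeloid markers were higher, with S100a8 2.02-fold (list adjusted p = 0.0072, adjusted p = 0.020 with an estimated correlation, but 0.0548 with the dim filter; 2 of 15 members called, 3 adjusted over the list alone), and B cell markers passed at 0.0072 with 1 of 14 members, H2-Aa, called (3 adjusted over the list alone, adjusted p = 0.22 with an estimated correlation, 0.0502 without Raptor-deficient 8 h replicate 1). In that list 3 members were called without replicate 1 of unstimulated or 24 h Raptor-deficient cells. Without wild-type unstimulated replicates 1 or 4, Raptor-deficient 8 h replicate 4 or Raptor-deficient 24 h replicate 2 there were 2. Alpha beta CD4 T cell markers had 3 of 11 lower (4 adjusted over the list alone), among them Thy1 (1.62-fold) and Cd6, with adjusted p = 0.0018 (adjusted p = 0.020 with an estimated correlation; 5 lower without Raptor-deficient unstimulated replicate 1). The lists of NK cells, regulatory, memory and gamma delta T cells and erythroid cells were not called. In all, 2207 genes were called at 8 h, 707 higher and 1500 lower, 80 with a fold of at least 2. With cyclic loess the split was 912 higher and 1210 lower. Of 1155 called genes with over 1 probe set, 8 had called probe sets of opposite direction.

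At 24 h the cell cycle genes that had risen in wild type were far lower in Raptor-deficient cells. Mki67 averaged 10.98 ± 0.03 in wild-type and 6.94 ± 0.22 in Raptor-deficient cells (SD, n = 4 each, 16.5-fold lower, adjusted p = 6.7e-15), and Birc5, a survivin gene of mitosis, 9.88 ± 0.18 and 5.85 ± 0.11 (16.3-fold lower). Of 34 G2 and M phase genes 33 were lower and 0 higher (34 and 0 adjusted over the list alone), with a median of -2.12. Of 39 G1 and S phase genes 34 were lower and 0 higher (34 and 1 adjusted over the list alone), with a median of -1.27, among them the replication genes Cdc6 (10.6-fold) and Mcm10 (4.89-fold). One-carbon, serine and nucleotide synthesis genes were lower in 20 of 23 cases, with Rrm2, a subunit gene of ribonucleotide reductase, 11.2-fold lower, and glycolysis genes in 15 of 17, with Tpi1 3.35-fold lower, each with 0 higher (22 and 16 lower adjusted over the list alone). Fatty acid synthesis (10 of 13, Scd1 3.22-fold), sterol synthesis and uptake (12 of 19, Fdps 2.09-fold), oxidative phosphorylation (27 of 54) and mitochondrial translation (24 of 30, Gfm1 2.08-fold) were also lower, with 0 members higher in each (11, 16, 34 and 25 lower adjusted over the list alone). Without Raptor-deficient 24 h replicate 4, 6 fatty acid synthesis genes were lower. These 8 lists passed camera with adjusted p of 1.9e-06 or less, and with an estimated correlation at 0.027 or less.

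Other groups at 24 h had lists that passed only with the preset correlation. The tricarboxylic acid cycle (9 of 18 lower, 1 higher; 11 and 1 adjusted over the list alone) and ribosome biogenesis (13 of 38 lower, 0 higher; 20 and 1) lists passed at 0.00090 and 7.6e-05, with adjusted p = 0.15 and adjusted p = 0.14 with an estimated correlation. The 1 higher member of the first was not called in 17 of the 24 fits with 1 sample left out, which left out wild-type unstimulated replicates 1 or 4, a wild-type 8 h sample, Raptor-deficient 8 h replicates 1, 2 or 3, or a 24 h sample. The unfolded protein response list passed at 0.0045 (10 of 22 lower, 3 higher, 12 and 3 adjusted over the list alone, adjusted p = 0.056 with an estimated correlation), with Sdf2l1 2.83-fold lower and Dnajb9 1.84-fold higher. Naive and quiescence genes were higher in 15 of 24 cases and lower in 3 (17 and 3 adjusted over the list alone), with Klf6 2.56-fold, Txnip 2.40-fold and Klf2 2.21-fold higher (8.3e-07, adjusted p = 0.089 with an estimated correlation). Activation genes were higher in 18 of 39 cases and lower in 8 (19 and 10 adjusted over the list alone; 0.0048, adjusted p = 0.14 with an estimated correlation), with Xcl1 11.8-fold, Nr4a1 2.02-fold and Cd69 1.80-fold higher, Il2 1.70-fold lower and Il2ra not called (adjusted p = 0.121). Interferon-stimulated genes passed at 7.6e-05 with 11 of 26 higher and 1 lower (15 and 2 adjusted over the list alone; adjusted p = 0.20 with an estimated correlation), with Ifit1 3.30-fold higher. That list had 7, 6, 6 and 7 members higher without wild-type 24 h replicates 3 and 4 and Raptor-deficient 24 h replicates 1 and 3, each left out alone, and 2 lower without Raptor-deficient unstimulated replicate 1 or Raptor-deficient 24 h replicate 3. Lysosome and autophagy genes passed at 0.021 with 11 of 31 higher and 5 lower (14 and 8 adjusted over the list alone, adjusted p = 0.14 with an estimated correlation), and not without replicate 1 of both 24 h groups (0.0757), and had 3 lower without wild-type 24 h replicate 3 or Raptor-deficient 24 h replicate 2. Cytosolic ribosomal proteins passed at 0.0072 with 5 of 32 higher and 1 lower (the same adjusted over the list alone, adjusted p = 0.25 with an estimated correlation), and not with cyclic loess (0.0930), and had 3 higher without wild-type 24 h replicate 2 or Raptor-deficient 24 h replicates 1 or 4.

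Single regulators at 24 h stood out among lists that were not called. In the helper lineage list (6 of 26 higher, 4 lower, 7 and 4 adjusted over the list alone, adjusted p = 0.21) Gata3 was 2.52-fold and Bcl6, a follicular helper factor gene, 2.38-fold higher, and Tbx21 3.32-fold lower. In the hypoxia list (4 of 19 higher, 2 without wild-type 24 h replicate 1, 7 lower, 5 and 8 adjusted over the list alone, adjusted p = 0.16) Ndrg1 was 3.17-fold higher and Ak4 3.16-fold lower, and Hif1a itself was 1.94-fold lower. Rragd was 2.84-fold higher and Rictor, which encodes the defining subunit of mTORC2, higher by 0.67 on the log2 scale in the list of PI3K, Akt and mTOR components (5 of 21 higher, 2 lower, adjusted p = 0.21). Asns, an amino acid synthesis gene, was 2.97-fold lower and Ddit3, a stress factor gene, 2.12-fold higher in the amino acid list (4 of 31 higher, 9 lower, adjusted p = 0.17). The p53 target list (5 of 17 higher, 3 lower, adjusted p = 0.67) held Trp53inp1 2.04-fold higher, and its median, mean and test differed in sign, as they did for memory T cell markers. Myc was 1.42-fold higher, Slc2a1 1.77-fold lower and Hk2 1.58-fold lower, and Irf4, Il4ra and Srebf2 were not called (adjusted p = 0.522, 0.692 and 0.904).

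B cell markers were higher at 24 h beside these groups, with 4 of 14 called and 0 lower (4 and 0 adjusted over the list alone; adjusted p = 0.00082, adjusted p = 0.18 with an estimated correlation), led by Pax5 (2.59-fold), and the immunoglobulin gene Igkj1 was 5.49-fold higher. Of the 4, 2 were called without Raptor-deficient 24 h replicate 1, where Fcer2a had adjusted p = 0.0897 and Cd79a 0.235, and 2 without wild-type 24 h replicate 4 (0.0700 and 0.112). Without replicate 1 of both 24 h groups these 2 genes had adjusted p = 0.0655 and 0.196. Cd79a also lost its call with cyclic loess (0.0533), with an intensity trend and robust prior (0.0539), and with adjusted p of 0.0501 to 0.124 without wild-type unstimulated replicate 3, wild-type 8 h replicate 4, wild-type 24 h replicates 2 or 3, Raptor-deficient 8 h replicate 4 or Raptor-deficient 24 h replicate 2. Igkj1 was at 8.67 in Raptor-deficient 24 h replicate 1 and at 7.21 to 7.44 in the rest of its group. Among the largest rises were also Akr1c18 (6.35-fold), Ccr8 (4.90-fold) and Trpm1 (4.03-fold). The lists of myeloid cells (3 of 15 higher, 1 without wild-type 24 h replicate 4 or Raptor-deficient 24 h replicate 2), NK cells (2 of 9), regulatory T cells (4 of 8 higher, 2 lower), memory or effector cells (3 of 14 higher, 2 lower, 1 lower without wild-type 24 h replicates 2 or 4 or Raptor-deficient 24 h replicates 1 or 2), erythroid cells (0 of 7), gamma delta and NKT cells (0 of 5) and alpha beta CD4 T cells (1 of 11 lower, 2 without Raptor-deficient unstimulated replicate 1) were not called, with adjusted p of 0.10 or more. The pair of CD8 markers, with 0 called and a median of -0.04, was too short to test. In all, 3671 genes were called, 1428 higher and 2243 lower, 407 with a fold of at least 2. Of 1875 called genes with over 1 probe set, 28 had called probe sets of opposite direction, and Ccnd3 was the member of the pathway lists among them.

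**Figure D2:**
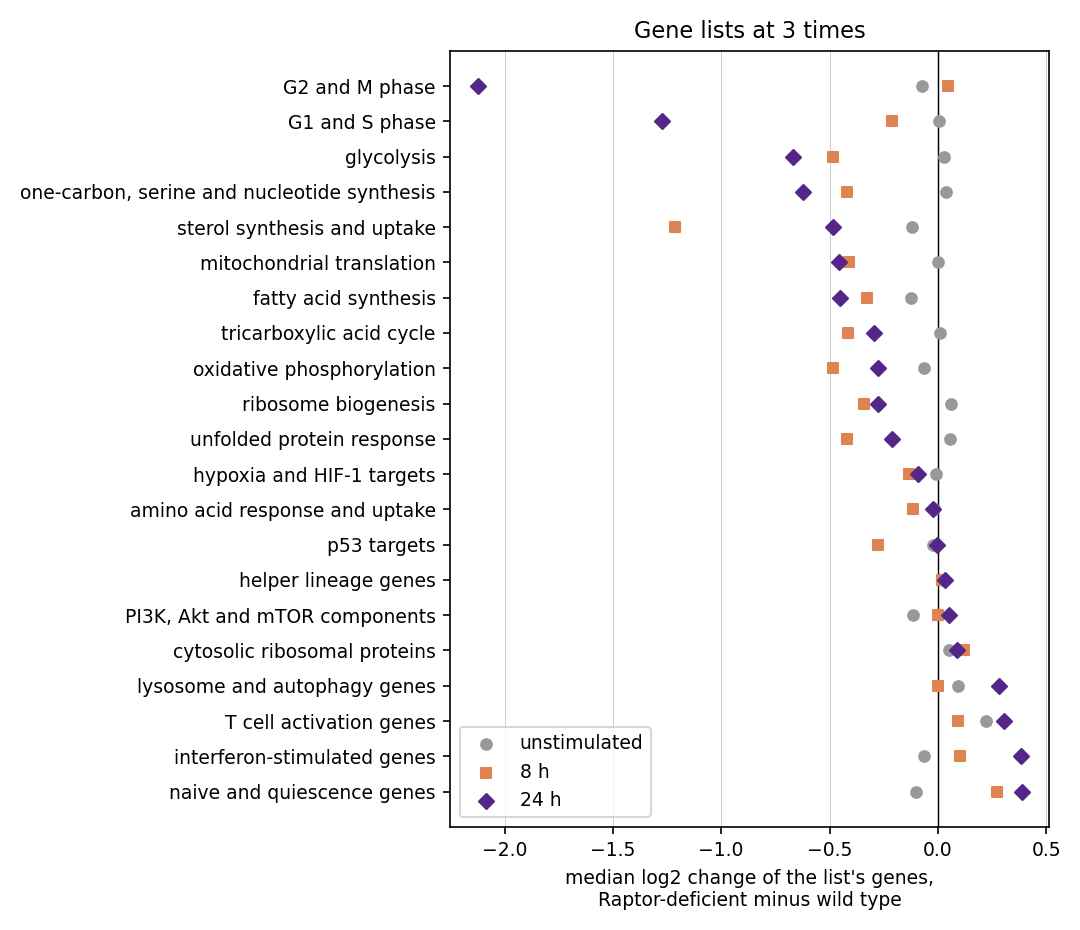
Each row is 1 of the 21 pathway lists and each mark the median log2 difference, Raptor-deficient minus wild type, of its measured genes at 1 of the 3 times. Sterol synthesis and uptake lies lowest at 8 h (-1.21) and G2 and M phase lowest at 24 h (-2.12).

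The 8 h and 24 h comparisons had 433 genes higher at both times, against 59.1 for independent lists, and 923 lower at both, against 197. They share no samples, but same-numbered samples may share animals or material, as wild-type Slc15a2 kept its low and high replicates at all 3 times, and the values for independent lists leave that out. This was checked after seeing the data, with the 8 h difference from 2 replicate numbers and the 24 h difference from the other 2. Over 6 such choices the covariance across genes averaged 0.0481, against 0.0485 with the same 2 numbers at both times. The genes shared averaged 86.2 higher and 168 lower, against 118.5 and 247.7 with the same numbers, where both differences also share 1 estimate of the spread. These smaller fits called fewer genes. Independent lists of their sizes would share at most 10.4 higher and 50.0 lower with other numbers, and 22.7 and 103 with the same. Sterol genes such as Stard4 and glycolysis genes such as Ldha were lower at both times, and Xcl1, Ccr8, Satb1 and Ikzf2, which encodes Helios, higher at both. Across genes the log2 differences at the 2 times correlated with a Pearson r of 0.50 and a Spearman rho of 0.52, where genes are not independent. Between unstimulated cells and 24 h, 57 genes were higher at both, against 10.02 for independent lists, and 76 lower at both, against 27.8. Across genes these 2 differences correlated weakly, with a Pearson r of 0.095 and a Spearman rho of 0.048. The covariances of the same check averaged 0.00618 with other and 0.00728 with the same numbers. In it the genes shared averaged 7 higher and 6.17 lower with other numbers, and 10 and 6.83 with the same. With other numbers independent lists would share at most 1.75 higher and 6.60 lower, the latter in a choice that shared 17. At all 3 times 83 genes were called, 70 of them in 1 direction, 33 higher and 37 lower, among them Fosl2, Rragd, Myb and Cd69 (higher) and Map3k5, Atxn1 and Dnajc15 (lower).

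The response itself, compared between genotypes, was smaller in Raptor-deficient cells for most of the genes that changed at least 2-fold in wild type. At 8 h the slope across these 1830 genes was 0.776 ± 0.043 (SD, n = 4), and 89.8% of them changed less. At 24 h it was 0.683 ± 0.042 over 2797 genes, with 89.4% changing less. Choosing the genes in the same wild-type samples lowers such a slope and raises such a share. With genes chosen in wild-type replicates 1 and 2 and changes set against those of replicates 3 and 4, the slopes were 0.734 for Raptor-deficient cells and 0.888 for wild-type replicates 1 and 2 at 8 h, and 0.667 and 0.952 at 24 h. With the roles of these replicates exchanged they were 0.83 and 1.14 at 8 h, and 0.702 and 1.05 at 24 h. With genes chosen in 2 wild-type replicates, and 2 Raptor-deficient replicates set against the other 2 wild-type ones, a check added after seeing the data, 70.4% to 89.4% changed less at 8 h and 80.2% to 88.5% at 24 h. With no difference as many genes would change less as more, but the 2 pairs of wild-type replicates differed too. In Raptor-deficient cells 5612 genes were called at 8 h and 6677 at 24 h.

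Sterol genes also led the tested difference between genotypes in the 8 h response, with 14 of 19 lower and 0 higher (17 and 0 adjusted over the list alone; adjusted p = 3e-29). The rise of Cyp51 differed by -1.81 on the log2 scale (adjusted p = 1.54e-07), and Il2, Hif1a and Sdf2l1 differed by -1.37, -1.11 and -1.30. Fasl had the largest negative difference, -2.35, and Ccr8 the largest positive one, 2.29. Cd69 differed by -0.75, and its level was already higher in unstimulated Raptor-deficient cells. Klrd1 and Slc2a3, lower in unstimulated Raptor-deficient cells, differed by 1.34 and 1.29; the lower unstimulated level of Slc2a3 (-0.796 on the log2 scale) was not called with only the unstimulated samples in the fit (adjusted p = 0.0848). In all, 1076 genes differed, 331 with a higher and 745 with a lower response, 84 by a fold of at least 2 (18 and 66). The last count was 148 (24 and 124) without Raptor-deficient unstimulated replicate 3 and 216 (26 and 190) without replicates 2 and 3 of that group. The count was 548 when only these 4 groups entered the fit and 1653 without Raptor-deficient unstimulated replicate 3, and cyclic loess gave 426 higher and 618 lower.

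For the 24 h response the tested difference covered 2270 genes, 900 with a higher and 1370 with a lower response, 446 by a fold of at least 2. Cell cycle genes led it, with 32 of 34 G2 and M phase and 34 of 39 G1 and S phase genes lower and 0 higher (32 and 35 lower adjusted over the list alone; adjusted p = 1.5e-66 and 5.8e-45), and Mki67 at -4.19 and Birc5 at -4.03. Tbx21 differed by -2.52 and Gata3 by 1.31 (adjusted p = 0.000774 and 0.000565). Xcl1 had the largest positive difference, 3.42. Between 8 h and 24 h, 774 genes changed differently, 227 higher and 547 lower, a count of 1294 with array weights. In that interval sterol genes gained in Raptor-deficient relative to wild-type cells, with 11 of 19 higher and 0 lower (15 and 0 adjusted over the list alone; adjusted p = 3.4e-16, adjusted p = 0.00016 with an estimated correlation), and Cyp51 at 1.44, while Mki67 was at -4.21 and Aurkb at -4.07.

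**Figure D3:**
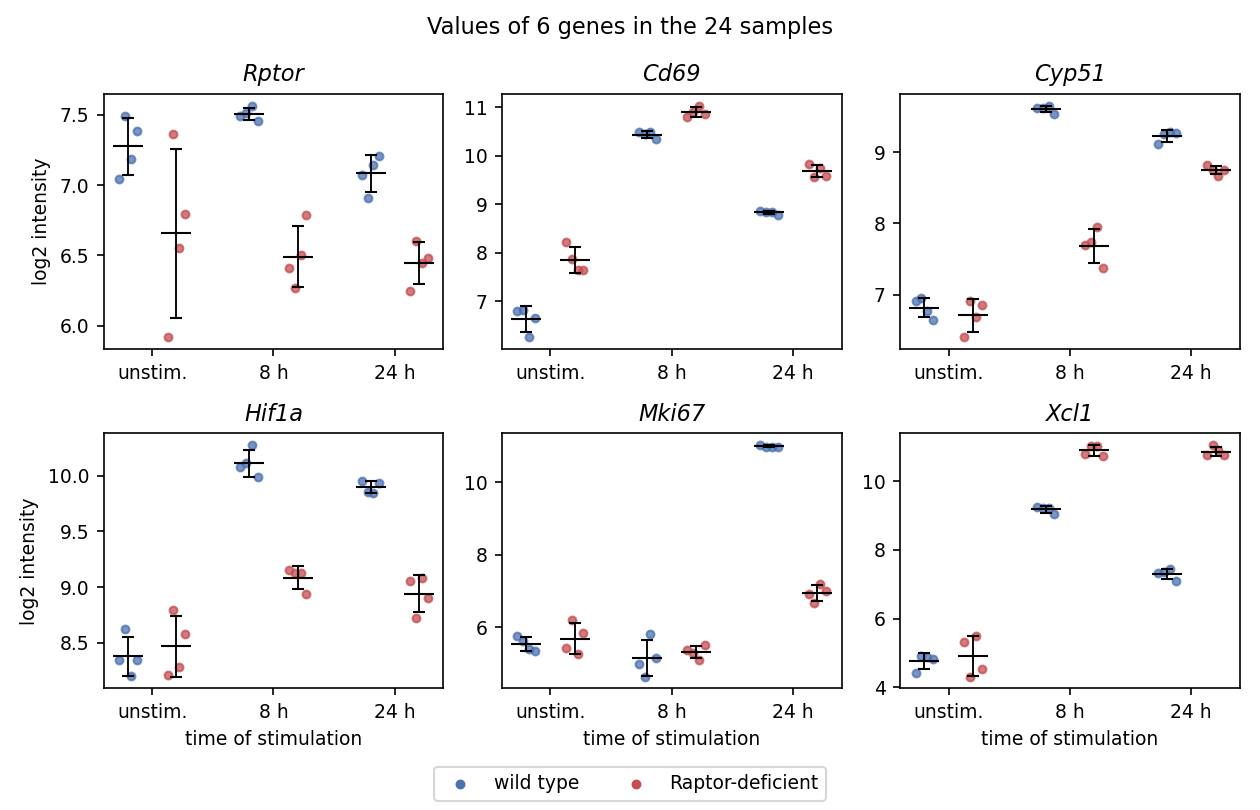
Log2 intensities of 6 genes in each of the 24 samples (points, 4 per group), with the mean and SD of each group (black). Mki67 rises at 24 h to 10.98 ± 0.03 in wild-type and 6.94 ± 0.22 in Raptor-deficient cells, and Cyp51 at 8 h to 9.61 ± 0.05 and 7.69 ± 0.24.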

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

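Of the tests on the 3 patterns below, those on a common delay, on the share of responding cells and on RNA of another cell type were chosen after the results were seen. Differences between genotypes in a response were tested as interaction terms with limma: 1076 genes at 8 h, 2270 at 24 h and 774 between 8 h and 24 h. The largest were Ccr8 (2.29 on the log2 scale) and Fasl (-2.35) at 8 h, Xcl1 (3.42) and Mki67 (-4.19) at 24 h, and Akr1c18 (2.20) and Mki67 (-4.21) between 8 h and 24 h.

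Whether random splits give as many genes was tested for each count with fits to the compared groups alone. For the 8 comparisons of 2 groups, 1 of the 35 splits, the real one, gave as many genes, the smallest share that 35 splits allow. That argues against chance at this level, but any other difference between the 2 groups would give it too. For unstimulated cells it covers the 52 genes of that fit, not the 332 of the shared fit. Real counts and highest counts of other splits for Raptor-deficient against wild type were 52 and 2 unstimulated, 2536 and 0 at 8 h, and 4670 and 0 at 24 h. They were 6995 and 1 for wild type at 8 h, 8831 and 0 at 24 h, 5393 and 0 for 24 h against 8 h, and 4428 and 0, and 5638 and 0, for Raptor-deficient cells at 8 h and 24 h. For the differences in response, 4, 2 and 4 of 100 splits, the real one included, gave as many genes at 8 h, at 24 h and between these times. The real counts were 548, 1979 and 1155, and the highest others 849, 2280 and 1521. Each of the larger splits kept the real genotype groups at one of the times, as labelled or with all 4 labels exchanged.

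The first pattern is the set of 70 genes that differ between genotypes in 1 direction at all 3 times. The wild-type label gives a strain and the Raptor-deficient label none. Strain DNA kept beside the targeted allele is argued against as the source of most of these genes. Of them, 0 lay among up to 100 measured genes on either side of Rptor. With 0.685 expected there by number, 0 cannot show fewer than by chance, and a longer stretch was not tested. Segments elsewhere stay open: 11 of the 70 had another of them among the 10 nearest measured genes on either side, such as Tnfaip3, Map3k5 and Myb, or Dnajc15 and Epsti1, against a median of 6 and a 95th percentile of 11 in 10000 random draws. By that count such segments and the loss of Raptor, which was not tested separately, cannot be told apart.

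The second pattern is unstimulated Raptor-deficient replicate 1, which stands apart with 342 genes at least 2-fold higher than in the other 3 replicates, among them Arsb (8.64 against 4.42) and Cryab (9.43 against 6.21). RNA from one of the listed cell types as the whole cause is argued against. The highest medians among the cell type lists in that library were 0.283, for the pair of CD8 markers, and 0.256, for B cells. These lists cannot speak for cells outside them. Alpha beta CD4 T cell markers had a median of -0.305 there, so a small admixture stays open. Uneven amplification or labelling of single fragments may account for it, since 175 other probe sets of the same genes had a median change of -0.0242 where the chosen ones rose by a median of 1.36. No biological explanation was tested, as no group of the design sets this sample apart.

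The third pattern is that Raptor-deficient cells at 24 h fell short of wild type in some lists and not in others. A smaller share of cells that respond at all is argued against: on the linear scale the G2 and M phase genes reached a median of 0.022 ± 0.004 of the wild-type change and activation genes 1.16 ± 0.11, a difference of 1.14. A delay common to all responding genes stays open. The slope of their distance from wild type at 8 h on the wild-type change from 8 h to 24 h differed by 1.28 between the highest and lowest lists, ribosome biogenesis and hypoxia, but lists that change early and late would differ under a delay too. A delay with steady rises between the sampled times would put genes still rising in wild type on 1 side of the wild-type 8 h level. Of 949 genes that rose in both intervals and were not called in unstimulated cells, 276 were called above that level in Raptor-deficient cells at 24 h and 38 (4.004%), such as Gfm1 and Sdf2l1, below it. Those 38 go against such a delay, but they fall short of the 10% on each side set as the bound. With no times between 8 h and 24 h, a delay and a loss of Raptor that affects gene groups differently cannot be told apart.

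Single samples far from the other 3 of their group appeared in 31 of the 405 groups of 4 values examined, where chance gives about 1 in 20, or 20.2. In unstimulated cells these were wild-type Klrd1 (6.79, replicate 3), Slc2a3 (7.87, replicate 4), Cd55 (9.86, replicate 4), Bcat1 (3.62, replicate 1) and Xcl1 (4.43, replicate 1), and in Raptor-deficient replicate 1 Cd4 (10.53) and Gata3 (6.80). At 8 h in wild type they were Ikzf2 (4.11), Id2 (6.90) and Aurkb (4.004) in replicate 2, Rgs1 (8.34) and Cd4 (10.45) in replicate 1, and Rora (4.82) in replicate 3. At 8 h in Raptor-deficient cells they were Suclg1 (6.88) and Hif1a (8.94) in replicate 4, and Xbp1 (8.06) and Cd4 (9.81) in replicate 1. Wild-type cells at 24 h gave Mki67 (11.02), Slc16a3 (6.51), Hk2 (9.10), Rragd (6.32), Cyp51 (9.11) and the array median (5.18) in replicate 1, Fdps (8.64) and Il2 (11.06) in replicate 3, and Satb1 (9.07) and Ifit1 (5.11) in replicate 4. Raptor-deficient cells at 24 h gave Bcl6 (8.53) and Slc2a1 (9.16) in replicate 3, Trpm1 (6.58) in replicate 4 and Igkj1 (8.67) in replicate 1.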

How the results depend on the processing

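The alternatives that left out several samples were chosen after seeing the data. No call of a named gene and no list test that passed reversed its direction under an alternative, but the median of the alpha beta CD4 T cell list in unstimulated cells, -0.0386, was 0.0044 without Raptor-deficient unstimulated replicate 3. For the genes named, 1690 of 1718 values from alternatives that left out no single sample kept direction and side of the threshold, as did 5098 of 5160 with 1 sample left out. Values called in neither fit count as kept. Leaving out a sample of a group outside the comparison does not change the log2 difference, so these shares overstate how stable the values were. For the lists these numbers were 2675 of 2838 and 7510 of 7656. With 1 sample left out, 68 of 124 counts of 1 or 2 called list members and 32 of 176 larger ones moved by over 1.5 times at least once. The unstimulated genotype count, 332, was 179 with array weights and 52 when only the groups compared entered the fit, and with 1 sample left out it ran from 196 (without wild-type unstimulated replicate 3) to 718 (without Raptor-deficient unstimulated replicate 3), with 207 and 216 without wild-type unstimulated replicates 1 and 2. The difference in the 8 h response, 1076 genes, was 548 with only the groups compared and ran from 753 to 1653 (without Raptor-deficient unstimulated replicate 3). Without Raptor-deficient unstimulated replicates 2 and 3 together these 2 counts were 718 (396 higher, 322 lower) and 1671. The difference between 8 h and 24 h, 774, was 1294 with array weights. The 8 h slope, 0.776, was 0.83 with genes chosen in wild-type replicates 3 and 4. Fits to fewer groups have fewer samples, but that alone cannot account for their counts. With only the compared groups, counts without unstimulated Raptor-deficient cells rose, such as 2207 to 2536 at 8 h. Counts with that group fell, such as 5612 to 4428 for the Raptor-deficient 8 h response. Replicates 1, 2 and 3 of that group had the largest residual SDs, and the shared fit uses 1 spread per gene. Its p-values for that group may be too small, as for the 332. The cause was otherwise not tested. The other 9 counts and slopes stayed within 1.5 times, or 1 SD for the slope, under every alternative run.

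Scaling moved the share of lower genes: 63.9% in unstimulated cells became 52.1% with centring, 68.0% at 8 h became 57.0% with cyclic loess, and 69.2% for the 8 h response became 59.2% with cyclic loess. With the replicate number as a replicate block, the 11 counts were 355, 2284 and 3725 for the genotypes at the 3 times, 6814, 8541 and 4906 for wild-type stimulation at 8 h, 24 h and between them, 5661 and 6731 for Raptor-deficient stimulation, and 1127, 2347 and 813 for the differences in response. Residuals of same-numbered wild-type and Raptor-deficient samples of the same time correlated across genes at 0.037 to 0.356, over 0.1 in 6 of 12 pairs. The numbers were not taken as pairs in the main fit. Correlations between times within a genotype were not computed, and Slc15a2 and Zfp287 followed the number there. All 12 correlations were positive, which with these 2 genes argues that same-numbered samples had something in common. Whether that was animals or material stays open. Without unstimulated Raptor-deficient and 8 h wild-type replicate 1 the genotype counts were 322, 2705 and 4237, and without unstimulated Raptor-deficient replicates 2 and 3, which lay further from their group than that wild-type sample, 718, 2597 and 4074. Without replicate 1 of both 24 h groups the 24 h count was 2841. Background correction of scanner files with slide as a block was not run. Dim genes sit near background, and 9479 genes passed the level filter.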

Other observations

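Liver transcripts marked replicate 1 of both 24 h groups. Of 37 measured genes abundant in liver, a list written after some of its values were seen, 20 were at least 2-fold higher in wild-type replicate 1 than in the rest of its group and 18 in Raptor-deficient replicate 1, and 0 in each of the other 22 samples. Mup3 was at 6.97 and 7.40 there and between 1.92 and 2.30 elsewhere, and Apoa1 at 7.67 and 7.82. The 25 genes listed before their values were seen had medians of 0.77 and 0.64 above the rest of the group.

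A few genes followed the replicate number across times. Zfp287 was at 6.64 and 6.91 in unstimulated wild-type replicates 3 and 4 and at 4.96 and 4.75 in replicates 1 and 2, and at 6.68 and 6.55 against 4.08 and 4.85 in Raptor-deficient cells. After stimulation the gap was smaller and the levels lay near background. In wild type they were 4.95 and 5.21 against 4.235 and 4.56 at 8 h, and 5.27 and 5.26 against 4.53 and 4.16 at 24 h. In Raptor-deficient cells they were 5.02 and 5.54 against 4.39 and 4.55, and 5.23 and 5.38 against 3.95 and 4.36. Slc15a2 kept its order of low and high wild-type replicates at all 3 times. These genes were chosen after their values were seen.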
